A study of Mus musculus with 2 samples.

How the data were processed

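One single-cell library of CD45-sorted cells from subcutaneous B16F10 tumours was analysed, with the sample tag library that labels its cells. Per the file headers, the authors made counts of unique molecules per cell and gene with the BD WTA Multiplex Rhapsody Analysis Pipeline 1.9.1, after its recursive substitution error correction, on GRCm38 with GENCODE vM19. The submitters' processing notes name GRCm39 instead, and the header was followed. The series text speaks of a targeted library, while the title, the extract protocol, the file header and the genes themselves show a whole transcriptome library, per the labels and per the file headers. The deposited table held whole-number counts for 24510 genes in 14899 cells, 745 of the genes without a molecule, and no value above 2596. Each cell also carried a deposited tag call, namely tag 8, 9 or 10, a multiplet or undetermined. The sample name beside the call repeated the tag in all 14899 cells and named no tumour genotype. The tags were therefore treated as 3 samples of unnamed genotype, no genotype was inferred from any value, and the comparison of knockout with wildtype tumours was not made. The labels do not say that the 3 mice of a genotype were tagged apart.

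Cells with a single tag, at least 200 detected genes and at most 25% mitochondrial molecules were kept, which left 10490 cells with a median of 3489 molecules. Doublets were treated first through the 1448 multiplet tag calls, which were left out. Scrublet (in scanpy 1.11.5) called 1 of 10491 cells (0.0095%), so it did not work here. From the multiplet rate, about 725 pairs of cells with the same tag were estimated among all single-tag cells before the filters (5.54%). How many of them remained among the kept cells was not estimated. Leaving out cells with known multiplets as neighbours took out 24 cells and only 29 of the 1271 filtered multiplets, so it did not work either. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components (scikit-learn 1.9.0), and a graph of 15 neighbours was clustered with the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0 with seed 0, into 22 clusters. The files used here give no cell annotation. Each cluster was named after the best of 24 cell types by markers fixed before the data were examined, as X-like, and only when at least 3 markers were detected in 10% of its cells with a mean log2 fold of at least 1. A cluster also stayed unnamed if its median depth was under 1/3 of the median of all clustered cells and its 10 leading genes held no marker of the type. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

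Molecules were summed per tag and class and divided by the total of the class, scaled as CPM, with exact Poisson 95% intervals, and shares of cells have exact Clopper-Pearson 95% intervals. Intervals cover counting error only, since cells are not replicates. Class contrasts used the log2 ratio of CPM within each tag, for genes with at least 30 molecules over both classes, and a count of 0 was set to the floor of 3 counts. Members of 15 gene lists with 151 genes, all found in the table and all fixed before the data were examined, could be named, except markers and the 10 leading genes of the clusters compared. The rule for other genes named the 5 with the largest spread between tags in the class with most cells, for the closing section. The rule was tested on simulated counts for macrophage-like against monocyte-like cells, over 10415 genes. It called 39 of 50 genes set 3-fold higher (78.0%) and 38 of 49 set 3-fold lower (77.6%), 49 of 50 and 48 of 49 at 8-fold, and 8 of 10217 unchanged genes (0.078%). The simulated counts held counting error only, around 1 shared profile, with no variation between cells or tags and no clustering. These rates are therefore not error rates of the rule in the real data. Alternatives used other scalings, with TMM factors from edgeR 4.0.16 in R 4.3.3 or without mitochondrial, ribosomal protein and immunoglobulin genes. Others thinned each cell to 1000 molecules, changed the Leiden resolution to 0.5 or 2.0, the minimum of genes to 500 or the mitochondrial limit to 10%, kept Scrublet calls, added undetermined cells, averaged CPM over cells or left out each tag. The alternatives chosen after seeing the data are named in the closing section. Coordinates come from GENCODE vM21 on GRCm38, the build of the file header but another release of the annotation. Tests of genotype were not run, since each unnamed genotype has 1 tag, and the class contrasts were described without a test.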

Results

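Immune cells were taken from subcutaneous tumours of B16F10 cells, a transplantable pigmented mouse melanoma line, sorted for the leukocyte antigen CD45 and profiled by single-cell whole transcriptome sequencing. The tumours had grown from wildtype cells or from cells with a knockout of Tyr or of Oca2, in 3 female C57BL/6 mice for each of the 3 tumour genotypes. Each genotype carried its own sample tag, and all cells went through 1 capture. Of 14899 cells, 4538 carried tag 8 (30.5%), 4232 tag 9 (28.4%) and 4320 tag 10 (29.0%), while 1448 were multiplets by tag (9.72%) and 361 had an undetermined tag (2.42%). The total molecule count was 21662592 in tag 8, 21753076 in tag 9 and 23683689 in tag 10, with medians of 2309.5, 2856.5 and 2954 molecules per cell. After filtering, 3336, 3485 and 3669 cells remained, with medians of 3224.5, 3671 and 3565 molecules. The mitochondrial filter set part of this, since 26.2%, 17.4% and 14.9% of the cells of tags 8, 9 and 10 exceeded it. Neither the labels nor the tag calls used here say which genotype carried which tag. Values are therefore given for each tag, no genotype was compared with another, and every interval covers counting error only.

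The 2 genes targeted in the tumour cells were read first, in the melanoma-like cells of each tag. Tyr (ENSMUSG00000004651.6), which encodes tyrosinase, the first enzyme of melanin synthesis, is a protein-coding gene of 5 exons in its first listed transcript, on chromosome 7 from 87424771 to 87493512 on the minus strand of GRCm38. Its level was 659 CPM (count over the class total, scaled) in tag 8 (exact 95% Poisson interval 626 to 692), 662 in tag 9 (621 to 703) and 714 in tag 10 (676 to 754), from 1555, 1016 and 1313 molecules. Oca2 (ENSMUSG00000030450.11), which encodes a melanosome membrane protein, is a protein-coding gene of 24 exons in its first listed transcript, on chromosome 7 from 56239760 to 56536518 on the plus strand. Its level was 39.0 CPM in tag 8 (31.4 to 47.8), 55.3 in tag 9 (44.2 to 68.4) and 32.1 in tag 10 (24.4 to 41.4), from 92, 85 and 59 molecules. These values rest on 50, 44 and 37 cells, Tyr was among the 10 genes leading the melanoma-like cluster, and a 3' molecule counted outside the edited part checks nothing. No tag was given a genotype from them.

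The first question was which immune cells the tumours held. Macrophage-like cells, named by complement genes such as C1qa and C1qb, made up 13.6% of tag 8, 16.7% of tag 9 and 15.6% of tag 10. T-like cells outside the CD8, regulatory and gamma-delta classes made up 10.5%, 12.2% and 13.8%, CD8 T-like cells 2.31%, 5.19% and 5.12%, and regulatory T (Treg)-like cells 2.37%, 2.58% and 2.45%. NK-like cells made up 5.37%, 9.47% and 8.83%, neutrophil-like cells 11.2%, 6.77% and 8.15%, and B-like cells 4.98%, 1.58% and 1.28%. Dendritic cells fell into conventional type 2 (cDC2)-like cells at 5.73%, 5.02% and 4.63%, CCR7+ (mature, migratory) DC-like cells at 4.35%, 3.47% and 3.24%, type 1 (cDC1)-like cells at 2.34%, 2.44% and 1.74% and plasmacytoid (pDC)-like cells at 1.47%, 1.35% and 1.04%. Despite the CD45 gate, 1.5%, 1.26% and 1.01% of the cells were melanoma-like and 0.36%, 0.34% and 0.35% fibroblast-like. The widest exact 95% Clopper-Pearson interval among the shares of these named classes was 15.5% to 18.0%, for macrophage-like cells of tag 9. The border between macrophage-like and monocyte-like cells moved with the clustering, and the median macrophage-like share of 15.6% ranged from 9.08% to 28.4%. The value of 15.6% was not typical of the settings. All others but Leiden resolution 0.5 gave 9.08% to 11.5% macrophage-like cells. They gave 8.56% to 12.5% monocyte-like cells, against 5.05% in the main clusters. Which of the 2 classes was larger was therefore left open. The median T-like share of 12.2% fell to 5.73% with finer clusters (Leiden resolution 2.0) and 5.98% with a minimum of 500 genes, and the median melanoma-like share of 1.26% was 0.64% without filters and 1.95% with finer clusters. The sum of macrophage-like cells, monocyte-like cells and an unnamed cluster led by Arg1 was 28.5%, 28.5% and 29.2%.

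**Figure D1:**
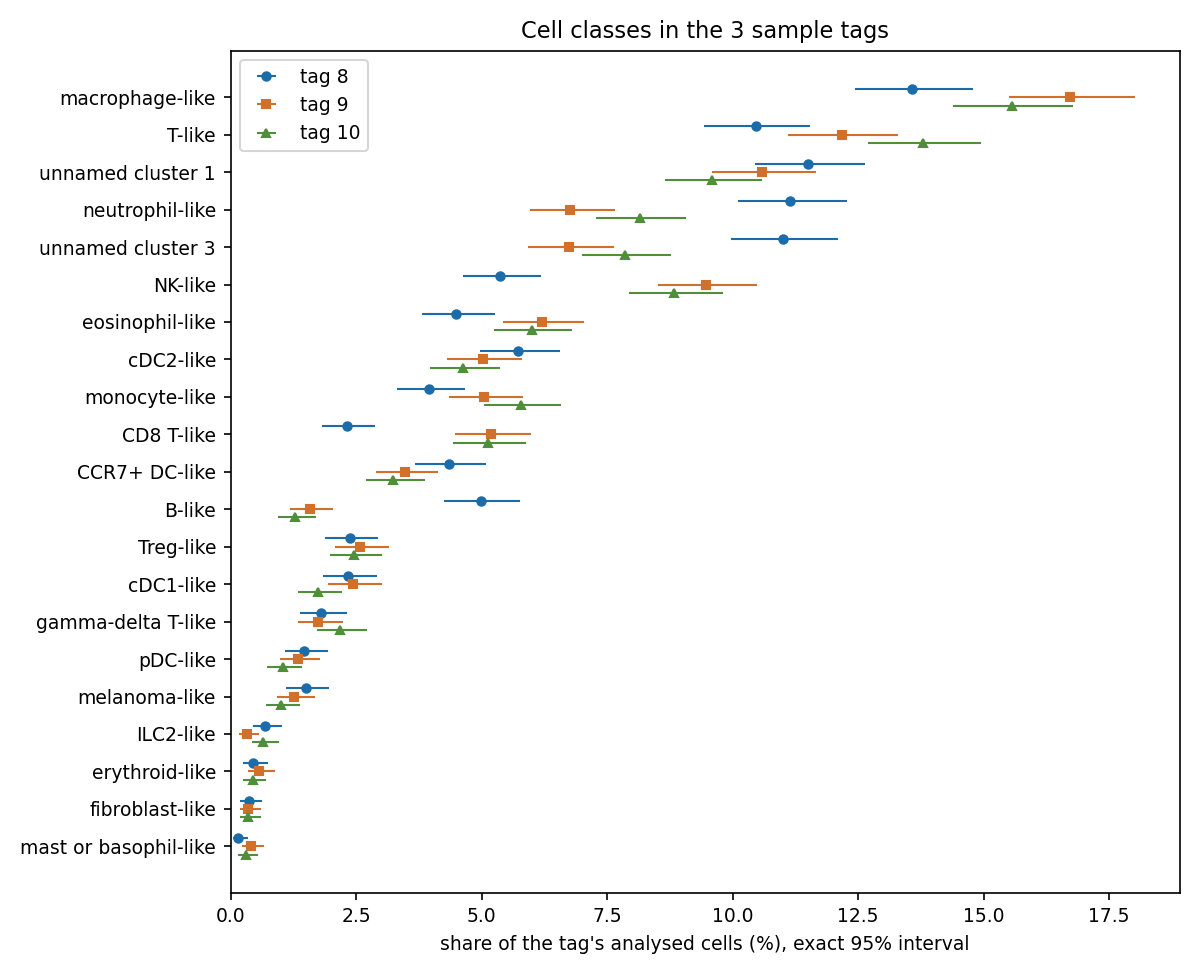
Share of each cell class among the analysed cells of sample tags 8, 9 and 10 (percent), with bars for the exact 95% Clopper-Pearson interval. Macrophage-like cells had a median share of 15.6%, above the 9.08% to 11.5% of all other settings but Leiden resolution 0.5. B-like cells had 4.98% in tag 8, 1.58% in tag 9 and 1.28% in tag 10.

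The study's labels name tumour-infiltrating immune cells, and the levels of immune regulators in them were read next. Cd274, which encodes PD-L1, the ligand of the checkpoint receptor PD-1, had 608, 1287 and 500.6 CPM in the neutrophil-like cells of tags 8, 9 and 10, 588, 649 and 581 in CCR7+ DC-like cells, 306, 436 and 338 in monocyte-like cells and 153, 522 and 274 in macrophage-like cells. Cxcl9, an interferon-induced chemokine that attracts T cells, had 163, 962 and 788 CPM in macrophage-like cells, and 655 over the tags together, which fell to 286 when the clustering left out the list genes. Cxcl10, a related chemokine, had 2019, 2914 and 1897.5 CPM in monocyte-like cells and 883, 1568 and 978 in macrophage-like cells. The interferon response genes Ifit2, Ifit3 and Rsad2 were among the 10 genes leading the monocyte-like cluster. Its Cxcl10 level is therefore not independent of how the cluster formed. Il10, an anti-inflammatory cytokine, had 833, 668 and 664 CPM in macrophage-like cells and 470.02, 331 and 267 in monocyte-like cells. Gzmb, the cytotoxic protease granzyme B, had 836, 1174 and 1147 CPM in NK-like cells and 1465, 1588.5 and 1041 in CD8 T-like cells. In CD8 T-like cells, Ifng, the cytokine interferon gamma, had 574, 241 and 307 CPM, and the inhibitory receptor gene Ctla4 had 283, 258 and 295. The class held 77 cells in tag 8, under the minimum of 100 set for comparing tags, and 181 and 188 in tags 9 and 10. With 1 tag for each unnamed genotype, none of these values was tested between tags.

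Cell classes of the same tag could be compared, in 5 contrasts fixed before the data were examined. A gene of the 15 fixed lists counted as higher or lower when its CPM differed at least 2-fold in the same direction in each of the 3 tags. With 3 tags no test was run. Chance alone gives 1 sign in all 3 tags for 25% of genes. Values are the median log2 ratio over the tags, with the range in parentheses. Genes that named or led the clusters compared were left out, among them Pdcd1 and Tox, which led the CD8 T-like cluster.

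CD8 T-like cells set against the other T-like cells compared 1 cluster with T-like cells whose CD4 and CD8 cells were not set apart. With finer clusters, and without the list genes in the clustering, CD4 T-like cells formed a class. That class alone was then the comparator. The CD8 chain gene Cd8b1 was found in 389 of 446 CD8 T-like cells (87.2%) and in 352 of the 1279 other T-like cells (27.5%). It was also found in 15.4% of Treg-like and 9.09% of CCR7+ DC-like cells. Neither of these is a clean background, since 18.7% of CCR7+ DC-like cells held 2 or more T receptor molecules. The classes also differed in depth, with medians of 8398 molecules in CD8 T-like, 2903 in T-like, 5713 in Treg-like and 6641 in CCR7+ DC-like cells. The shares of cells with Cd8b1 are therefore not at equal depth. Of 12 proliferation genes, 11 were higher, with Mki67, a marker of cycling cells, at 3.67 (3.25 to 3.78), Top2a, a DNA topoisomerase, at 3.42 (3.19 to 3.68) and Stmn1, a microtubule regulator, at 2.88 (2.79 to 3.16). Of 12 cytotoxic effector genes, 6 were higher, among them Prf1, which encodes perforin, at 4.28 (3.28 to 4.73) and the granule gene Nkg7 at 1.51 (1.13 to 1.57), which stood at 1.13 and was no longer 2-fold in every tag against T-like cluster 6 alone. The granzyme genes Gzmd, Gzme and Gzmf had 336, 247 and 445 molecules in CD8 T-like cells against 0, 1 and 1. In thinned cells all of them had too few molecules to compare. The call of Gzmd also ended with finer clusters, at 1.83, and against T-like cluster 6 alone. Of 9 checkpoint genes compared, 4 were higher, including the inhibitory receptor genes Lag3 at 3.22 (2.88 to 3.72) and Havcr2 at 2.86 (2.63 to 3.51) and the costimulatory receptor gene Tnfrsf9 at 2.71 (2.69 to 2.82). Of 12 glycolysis and hypoxia genes, 4 were higher, with the glycolytic enzymes Tpi1 at 2.28 (2.18 to 2.41) and Pgk1 at 1.88 (1.70 to 2.01), but the calls of the other 2, Ldha and Gapdh, ended with finer clusters, with Ldha at 0.69.

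Genes of resting and recirculating T cells were lower in the CD8 T-like cells. Of 5 progenitor and memory genes compared, 4 were lower, with Il7r, the receptor chain for interleukin 7, at -4.30 (-4.38 to -3.35) and Klf2, a transcription factor of lymphocyte migration, at -3.65 (-3.98 to -3.51). Of 11 type I interferon response genes, 9 were lower, with Isg15 at -1.67 (-1.81 to -1.60) and Rtp4 at -2.98 (-3.16 to -2.87), as were 5 of 11 interferon gamma response genes, with the transcription factor gene Irf1 at -1.73 (-1.79 to -1.73). Of 12 dissociation stress genes, 3 were lower, with Fos at -2.23 (-2.37 to -1.66), none was higher, and all 3 calls were lost with finer clusters, with Fos at -1.54 and Jun at -0.18. In all, 27 of 129 list genes were higher and 24 lower, against 9.34% and 6.61% of all genes. The lower calls fell most with finer clusters, where CD4 T-like cells alone were the comparator. The changed comparison and the changed clusters cannot be told apart there. In that setting 4 were lower, and all 9 type I and all 5 interferon gamma calls were lost. Isg15 stood at -0.89, Rtp4 at -1.13 and Irf1 at -1.21, under 2-fold in at least 1 tag. Clustering without the list genes, with the same comparator, gave 12 lower, 11 of them among the 24.

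NK-like cells set against CD8 T-like cells compared the main cytotoxic classes. Of 833 NK-like cells, 220 (26.4%) held 2 or more molecules of the T receptor genes, against 99.3% of CD8 T-like cells. This contrast was not repeated without those NK-like cells, so T cells within the NK-like class were not checked for. Of the checkpoint list, 4 of 9 genes were lower in NK-like cells, with Havcr2 at -5.51 (-5.93 to -5.01), Lag3 at -3.76 (-4.06 to -3.60) and Ctla4 at -1.96 (-2.89 to -1.91). In the same list 1 gene, Cd244a, was higher, but its call ended in thinned cells, at 0.79. Gzmk, a granzyme, stood at -4.09 (-4.15 to -3.90), and the costimulatory receptor gene Icos at -1.98 (-2.54 to -1.80). Vegfa, a growth factor of blood vessels, was higher in NK-like cells at 4.95 (4.66 to 5.47), with 629.7, 738 and 779 CPM in tags 8, 9 and 10. Tcf7, a transcription factor of memory lymphocytes, was higher at 1.75 (1.42 to 1.97), and so was Cd274 at 1.48 (1.39 to 1.49), but with finer clusters they stood at 0.87 and 0.96 and the calls ended. Of 12 proliferation genes, 5 were lower, with Ube2c at -1.66 (-1.74 to -1.55), but the calls of the other 4, Birc5, Ccnb2, Cdk1 and Rrm2, were lost with finer clusters, at -1.21 for Birc5 and -0.97 for Cdk1, near the 2-fold line. Of 12 dissociation stress genes, 5 were higher, with Jun at 1.96 (1.95 to 2.33), and the calls of Fos and Ier2 ended with finer clusters, where each stood at 0.97. In all, 16 of 133 list genes were higher and 15 lower, against 5.36% and 4.24% of all genes. With finer clusters 9 were higher, and the type I interferon gene Rtp4, at 1.18 in the main clusters, turned to -0.46.

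**Figure D2:**
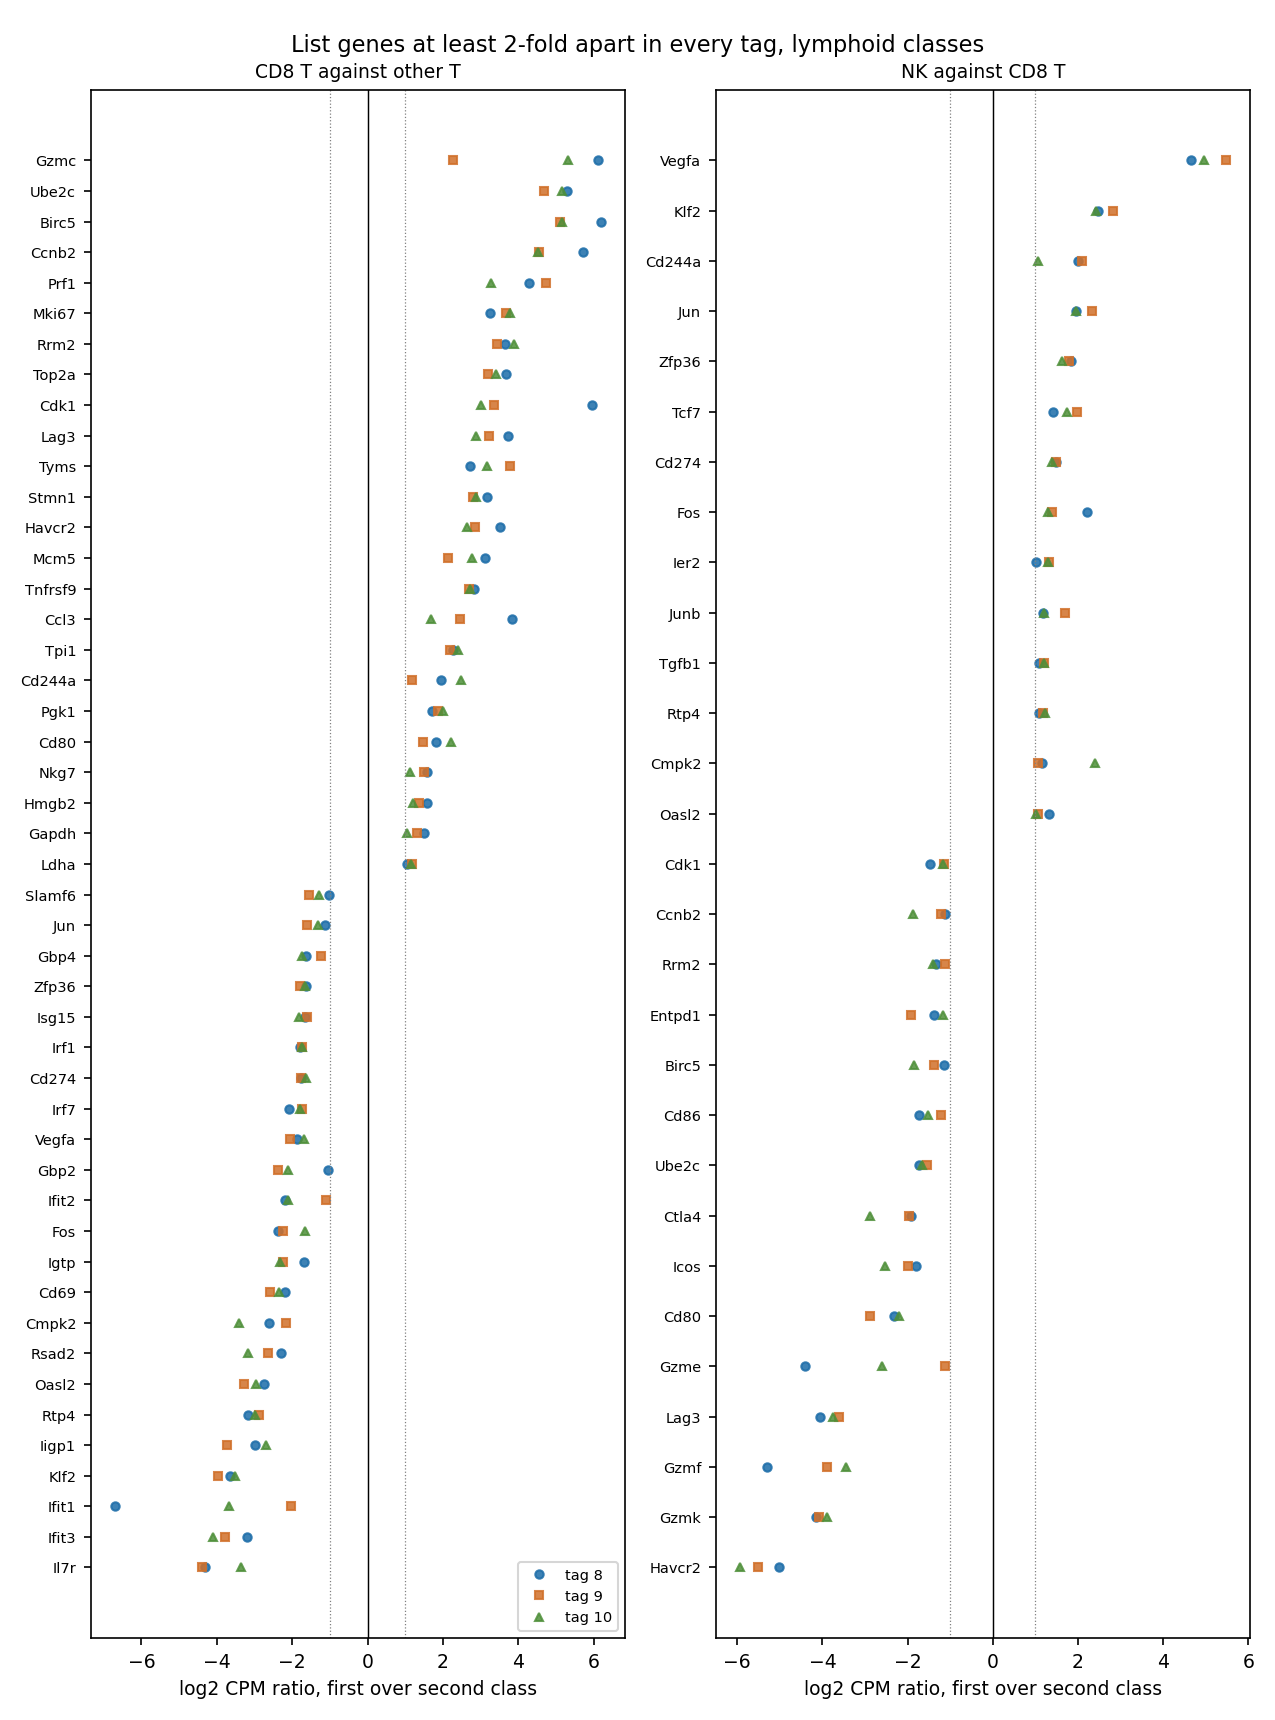
Log2 ratio of CPM in sample tags 8, 9 and 10 for list genes at least 2-fold apart in every tag, for CD8 T-like over other T-like cells (left) and NK-like over CD8 T-like cells (right). Genes with a count of 0 in a tag and 1 gene left out of the text are not drawn, and dotted lines mark 2-fold. Mki67 stood at 3.67 on the left and Vegfa at 4.95 on the right. The type I interferon calls on the left were lost with finer clusters, where CD4 T-like cells alone were the comparator.

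Macrophage-like cells were also set against monocyte-like cells, another phagocyte class. Of 10 genes of the suppressive macrophage list, 5 were higher, including Folr2, a folate receptor of tissue macrophages, at 3.82 (3.74 to 4.81), the lipid receptor gene Trem2 at 2.15 (2.15 to 2.62), Gpnmb, a lysosomal glycoprotein, at 2.65 (1.27 to 2.75) and Spp1, which encodes osteopontin, at 2.06 (1.70 to 2.17), which stood at 0.34 with finer clusters, where its call ended. The scavenger receptor gene Cd163 had 709 molecules in macrophage-like cells against 1, from 1607 against 520 cells. In thinned cells its call ended, with 28.05 CPM against 0 and a ratio of 0.64 set by the floor. The call of Gpnmb ended there too, at 2.37. Of 12 proliferation genes, 5 were higher, with Stmn1 at 1.77 (1.38 to 2.05), but thinned cells kept none of the 5 calls, as Stmn1 stood at 0.80 and the other 4 genes had too few molecules to compare. Of 8 type I interferon genes compared, 4 were lower, with the antiviral gene Mx1 at -2.69 (-2.79 to -2.55), Usp18 at -2.10 (-2.68 to -2.02) and Irf7 at -1.36 (-1.45 to -1.30), and other interferon genes led the monocyte-like cluster itself. With finer clusters 3 of these 4 calls were lost, with Usp18 at -1.21, Ifit1 at -0.71 and Irf7 at -0.51. In all, 11 of 130 list genes were higher and 7 lower, against 3.37% and 1.82% of all genes, with 11 lower without tag 9 and 4 higher once each cell was thinned to 1000 molecules. Without the 24 neighbours of known multiplets 14 were lower, 4 of them among the 7. Cxcl9 was higher at 1.79 (1.38 to 2.32), but turned to -1.78 when the clustering left out the list genes and to -1.85 without neighbours of known multiplets, while finer clusters gave 2.86, so its direction was left open.

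Neutrophil-like cells set against macrophage-like cells compared the main phagocyte classes. The median gene lay at -0.74 on the CPM scale and at -0.18 with TMM scaling. Cxcl2, a neutrophil-attracting chemokine, alone held 68102 CPM in neutrophil-like cells. Ratios are therefore given relative to the median gene. Of 10 inflammatory cytokine genes, 5 were higher on the CPM scale, with the chemokine gene Ccl3 at 4.54 (3.84 to 4.55), Cxcl2 at 3.39 (2.87 to 3.42), and the interleukin genes Il1a at 3.10 (2.80 to 3.13) and Il1b at 2.18 (1.85 to 2.84). Slc7a11, the cystine importer, at 4.91 (4.59 to 5.32) and Gsr, glutathione reductase, at 4.89 (4.36 to 5.51) were higher too, while the peroxiredoxin gene Prdx1 stood at -2.51 (-2.58 to -1.72). All 6 genes of MHC class II presentation were lower, with H2-Aa at -3.35 (-3.55 to -1.60) and the invariant chain gene Cd74 at -2.65 (-2.77 to -1.56). So were 5 of 10 suppressive macrophage genes, with Trem2 at -4.75 (-5.53 to -4.47) and Il10 at -2.91 (-3.16 to -2.43). Of 135 list genes, 21 were higher and 28 lower on the CPM scale, so 42.9% of the calls were higher, and of all genes 6.61% were higher and 26.6% lower. With TMM scaling 40 were higher and 22 lower (64.5%), and relative to the median gene 46 and 19 (70.8%).

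**Figure D3:**
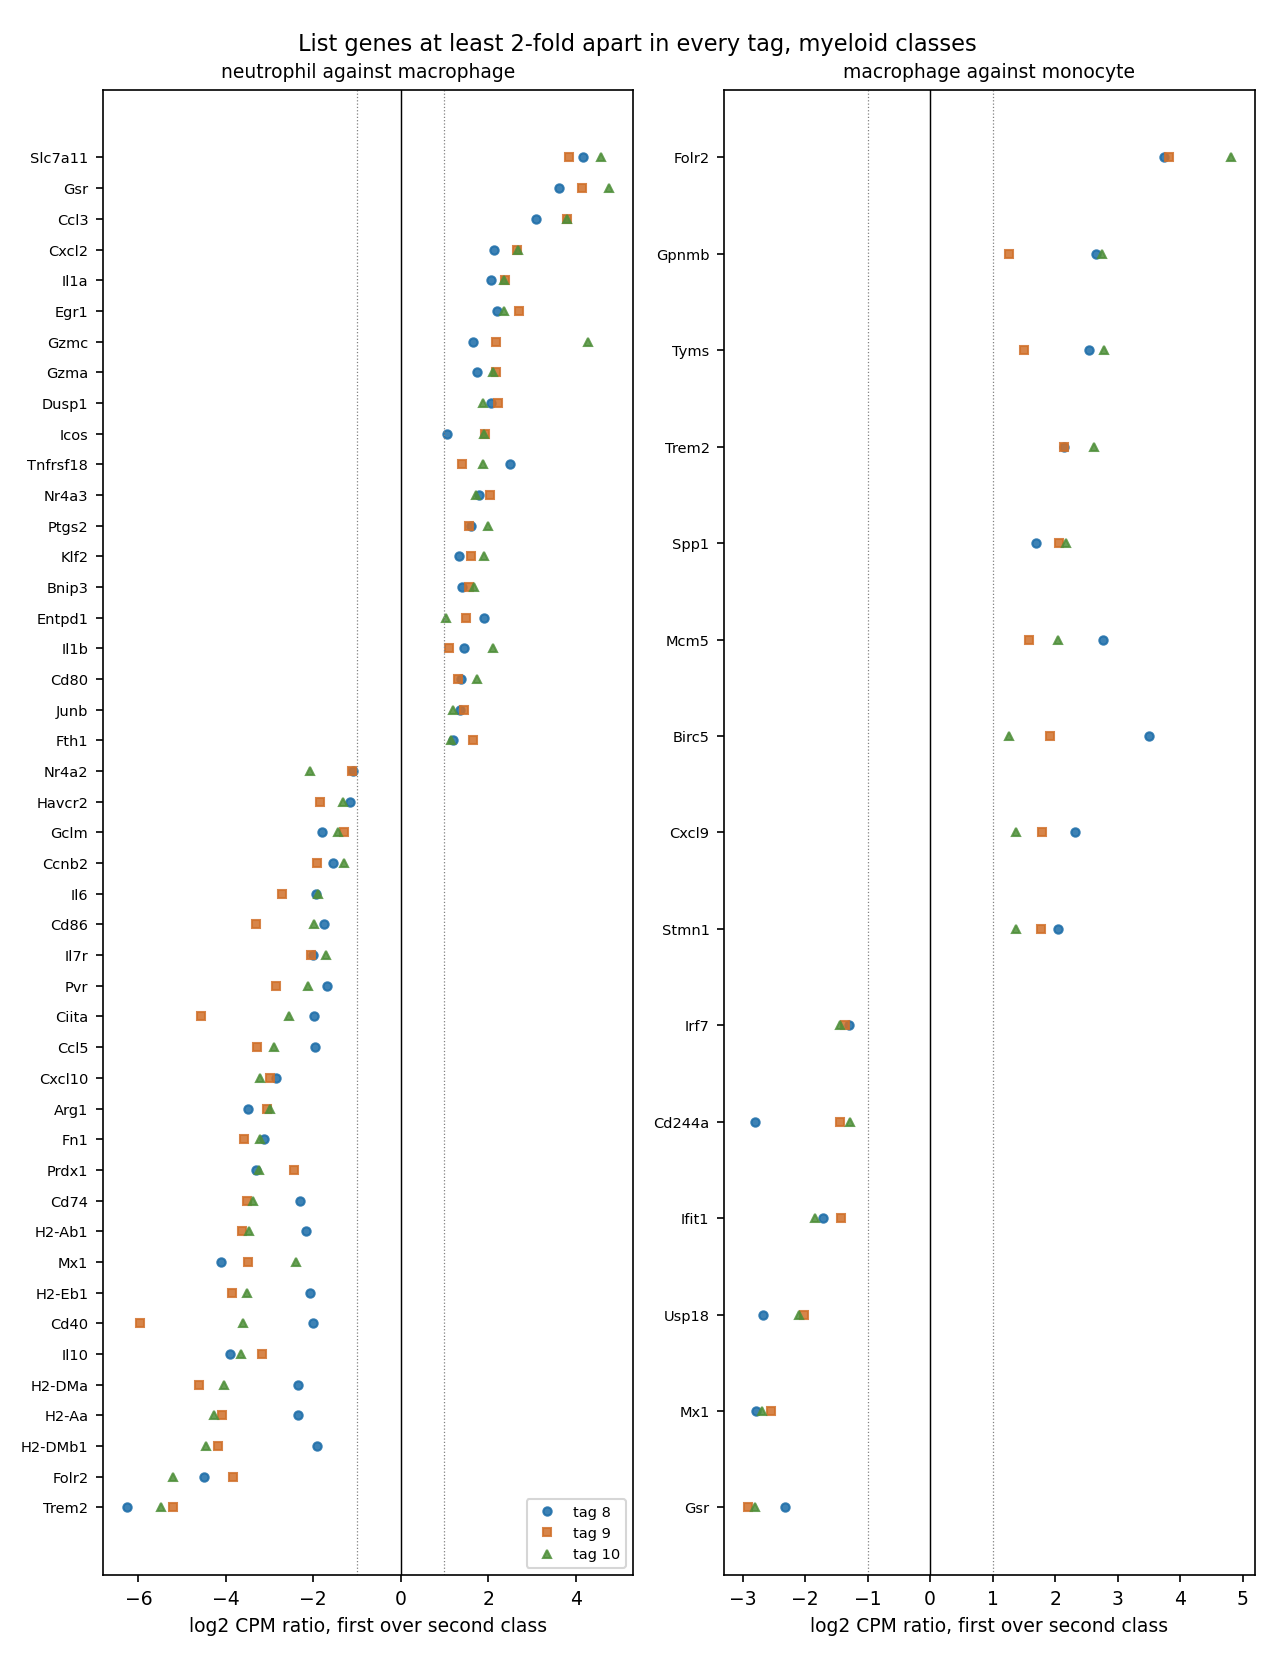
Log2 ratio of CPM in sample tags 8, 9 and 10 for list genes at least 2-fold apart in every tag, for neutrophil-like over macrophage-like cells (left, where the median gene lay at -0.74) and macrophage-like over monocyte-like cells (right). Genes with a count of 0 in a tag and 1 gene left out of the text are not drawn, dotted lines mark 2-fold, Folr2 stood at 3.82 on the right, and Cxcl9 on the right turned to -1.78 and -1.85 with other clusterings.

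CCR7+ DC-like cells set against cDC1-like and cDC2-like cells showed how mature dendritic cells differed from the others. Ccl5, a chemokine that attracts T cells, was higher at 5.11 (3.80 to 5.15), Tcf7 at 4.72 (4.51 to 5.37), Il7r at 1.77 (1.73 to 1.78) and Cd40, the costimulatory receptor engaged by helper T cells, at 1.44 (1.31 to 2.18). The receptor genes Tnfrsf9 and Tnfrsf18 stood at 3.22 (2.92 to 3.59) and 2.33 (2.02 to 2.50). Of 6 genes of MHC class II presentation, 3 were lower, with the peptide-loading gene H2-DMb1 at -3.13 (-3.37 to -3.11) and H2-Ab1 at -1.49 (-1.68 to -1.39), and so was Ciita, the class II transactivator, at -1.97 (-2.06 to -1.57). In all, 22 of 138 list genes were higher and 9 lower, against 6.74% and 6.30% of all genes, with 14 lower without tag 9 and 14 without tag 10. Transcripts typical of T cells were among the 22, including Gzmb at 4.29 (4.05 to 5.65), Nkg7 at 3.56 (3.29 to 3.60), Icos at 3.04 (2.25 to 4.14) and Ctla4 at 2.81 (1.56 to 3.61). In this class 72 of 385 cells (18.7%, exact 95% interval 14.9% to 23.0%) held 2 or more molecules of the T receptor genes Cd3e, Cd3d, Cd3g, Trac and Trbc2, against 4.48% of cDC2-like and 6.17% of cDC1-like cells, at medians of 6641, 5781 and 10469 molecules. Without such cells, Gzmb stood at 0.71, Icos at 0.38, Nkg7 at -1.30 and Ctla4 at -2.56, and 11 of the 22 higher calls and all 9 lower calls were kept, among 17 higher and 23 lower. Ccl5, Tcf7, Il7r, Cd40, Tnfrsf9 and Tnfrsf18 were among the 11.

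**Figure D4:**
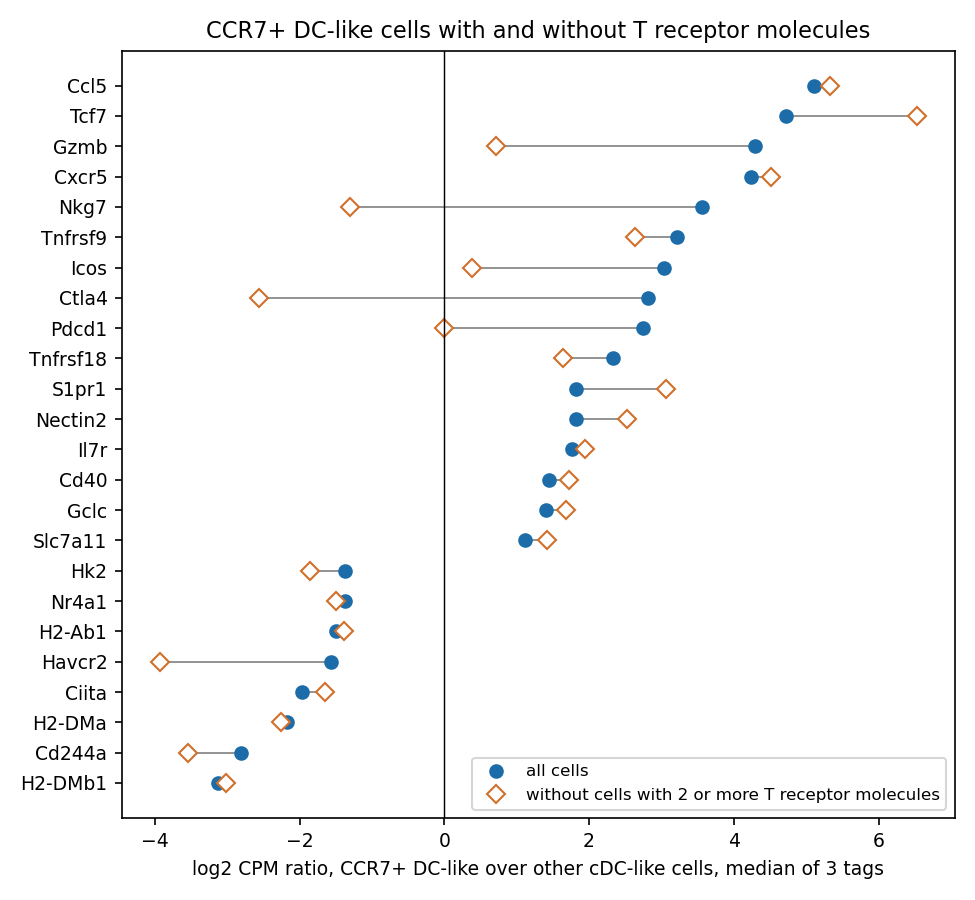
Log2 ratio of CPM in CCR7+ DC-like over other cDC-like cells, as the median of the 3 sample tags, for list genes called in all cells, with all cells (filled circles) and without cells that held 2 or more T receptor molecules (open diamonds). Ctla4 moved from 2.81 to -2.56 and Nkg7 from 3.56 to -1.30, and genes left with too few molecules and 1 gene left out of the text are not drawn.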

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

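In this part, the tests of free T cell RNA and of capture together, and the check of other minimum numbers, were chosen after the T cell transcripts had been seen, while the test of chance pairs and those of the undetermined cells were written before their results.

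The undetermined cells were set aside by the filter on tags, and their make-up drew attention because melanoma-like cells made up 62.9% of the 175 that passed the other filters. Of 240 melanoma-like cells in the clustering with undetermined cells, 110 had no determined tag (45.8%, exact 95% interval 39.4% to 52.4%). If the tags bind a surface antigen of immune cells, other cells without it should lack tags too, and 35.0% of fibroblast-like cells (14 of 40, 20.6% to 51.7%) were undetermined against at most 1.38% in any immune class, a result consistent with that explanation. A low molecule yield as the only cause was argued against, since 38.5% of the deepest melanoma-like cells (45 of 117, 29.6% to 47.9%) were undetermined, against 0.34% of the immune cells, although undetermined melanoma-like cells had a median of 22455 molecules against 44944 with a tag. The melanoma-like shares of the tags may therefore be too low, and the count of Tyr and Oca2 molecules in them incomplete. Whether the melanoma-like cells that had a single tag carried the right one was not checked.

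The multiplets by tag, also set aside, drew attention because 29 of them held transcripts of CCR7+ DC and of the T receptor together, as did 62 cells with a single tag. Free T cell RNA was argued against, since T receptor CPM was 12.6-fold (11.0 to 14.6) that of cDC2-like cells, and whole T cells captured with the dendritic cells fitted, since 96.8% (96.0% to 97.4%) of the T receptor molecules lay in 57 of the 385 cells. Pairs were called from counts alone, as cells with at least 10 molecules of CCR7+ DC marker genes and 5 of the T receptor genes. Chance pairs made after pooling would share a tag in 32.8% of cases, whereas 68.1% (57.5% to 77.5%) of the 91 pairs did, against 18 of 45 macrophage and T cell pairs (25.7% to 55.7%). With 9 choices of the minimum numbers of molecules, the lower bound lay above the random share in 9 and above the upper bound of the macrophage pairs in 7. A cell with a single tag could also be a single cell with both sets of transcripts, or a pair of which a tag was missed. Either would raise the share, and neither was checked. If they were true pairs, they could have formed before pooling, in the tumour or while cells were dissociated and tagged, which these data do not separate. Imaging of CCR7+ DC next to T cells in tissue sections would test formation in the tumour.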

How the results depend on the processing

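In this part, the alternatives without any filter, without neighbours of known multiplets, without the list genes in the clustering, with each T-like cluster apart, without cells holding T receptor molecules and with ratios relative to the median gene were chosen only after results had been seen.

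Shares of macrophage-like, monocyte-like, T-like and CD8 T-like cells depended on the clustering, with a median monocyte-like share of 5.05% in the main clusters. The median gamma-delta T-like share rose from 1.8% to 6.84% with at most 10% mitochondrial molecules. Shares of cDC2-like, cDC1-like and pDC-like cells moved beyond their interval in no setting that named them. Scalings changed few calls except for neutrophil-like against macrophage-like cells. Tag calls, the alignment and the 3 tags without replicates could not be varied. Count models with edgeR or DESeq2 were not run between tags, as 1 tag stands for each unnamed genotype. Class contrasts were ratios within each tag, and a model of class plus tag, which 3 tags allow, was not run on them. Why a share moved was not tested.

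Median shares over the tags are given first. Leiden resolution 0.5 gave 28.4% macrophage-like cells against 15.6% in the main clusters. Leiden resolution 2.0 gave 11.1% macrophage-like, 12.5% monocyte-like, 5.73% T-like, 7.12% CD8 T-like and 1.95% melanoma-like cells, and 25.5% for macrophage-like, monocyte-like and Arg1-led cells together. A minimum of 500 genes gave 10.4% macrophage-like, 11.4% monocyte-like, 5.98% T-like and 7.68% CD8 T-like cells. At most 10% mitochondrial molecules gave 11.5% macrophage-like, 9.13% monocyte-like, 8.61% T-like, 6.84% gamma-delta T-like, 23.7% all T-like, 6.91% eosinophil-like, 1.14% B-like and 0.9% melanoma-like cells. Without any filter there were 9.08% macrophage-like, 8.56% monocyte-like, 24.8% macrophage-like, monocyte-like and Arg1-led cells together, 9.97% T-like, 18.7% all T-like, 7.22% neutrophil-like, 7.38% NK-like, 5.09% eosinophil-like, 2.81% CCR7+ DC-like, 1.92% Treg-like and 0.64% melanoma-like cells. Scrublet calls kept, which added only 1 cell, gave 11.01% macrophage-like and 11.2% monocyte-like cells, and leaving out neighbours of known multiplets gave 11% and 10.2%. Clustering without the list genes gave 10.4% macrophage-like (10.37%), 10.1% monocyte-like, 6.24% T-like and 6.71% CD8 T-like cells. With undetermined cells added, 9.42% of all cells were macrophage-like, 10.4% (10.35%) monocyte-like and 2.25% melanoma-like.

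In melanoma-like cells, the median Tyr level of 662 CPM was 805 without mitochondrial, ribosomal protein and immunoglobulin genes, 528 with TMM scaling, 714 with thinned cells and 562 as a mean over cells, and Oca2 fell from 39.0 to 31.2 with TMM scaling. Thinning to 1000 molecules took the lower calls of CD8 T-like against other T-like cells from 24 to 13, the higher calls of NK-like against CD8 T-like cells from 16 to 9 and those of macrophage-like against monocyte-like cells from 11 to 4. Leiden resolution 2.0 gave 4 and 9 for the first of these contrasts and the second, with Ifit2 at 0.12 in the first, and Oasl2 at -0.03 and Rtp4 at -0.46 in the second. There, and in clustering without the list genes, the first contrast had CD4 T-like cells alone as its comparator. Each T-like cluster alone left 22 (cluster 5) and 24 (cluster 6) lower in the first. Clustering without the list genes gave 12 and 8, with Vegfa at 0.14 in the first and Rtp4 at -0.41 in the second, Cxcl9 at -1.78 in macrophage-like against monocyte-like cells, and 14 lower in CCR7+ DC-like cells. Leaving out neighbours of known multiplets gave 14 lower calls in macrophage-like against monocyte-like cells, with Cxcl9 at -1.85. Leaving out tag 9 gave 11 lower there, against 7 in the main clusters and 7 without tag 10, and 14 in CCR7+ DC-like cells, where leaving out tag 10 gave 14 too. Fewer tags ease the rule, so these counts could only rise for genes that kept enough molecules. For neutrophil-like against macrophage-like cells, 40 genes were higher with TMM scaling and 46 relative to the median gene, against 21. Leaving out cells with T receptor molecules gave 23 lower in CCR7+ DC-like cells, with Ctla4 at -2.56 and Nkg7 at -1.30.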

Other observations

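In this part, the genes looked for in the CCR7+ DC and T cell pairs were chosen after the pairs had been seen, and the tests of pigment transcripts were written before their results.

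One unnamed cluster, led by Arg1, which encodes arginase 1, and by Spp1, Fn1 and Mmp12, made up 11.0% of tag 8, 6.74% of tag 9 and 7.85% of tag 10. Vegfa had 915, 934 and 1015 CPM there in tags 8, 9 and 10, against 370.5, 372 and 417 in macrophage-like cells. Slc2a1, the glucose transporter GLUT1, had 408, 455 and 457 CPM against 135, 189 and 135, and Bnip3, a hypoxia-induced mitophagy gene, had 444, 409 and 504 against 126, 115 and 102. Hmox1, which encodes heme oxygenase 1, had 2226, 2462 and 4768 CPM against 1650.06, 786 and 1321. H2-Aa, an MHC class II chain, had 1243, 1585 and 1144 CPM against 3558, 5337 and 4984. The cluster was not among the contrasts, so no call was made.

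Eosinophil-like cells had 859, 947 and 796 CPM of the cystine importer gene Slc7a11 and 553, 620.1 and 599 of Vegfa in tags 8, 9 and 10. Gamma-delta T-like cells, led by Il17a, which encodes interleukin 17A, had 2358, 2259 and 1897 CPM of Icos and 1418, 1163 and 1119 of Il7r. Another unnamed cluster, led by Malat1, made up 11.5%, 10.6% and 9.59% of the tags at a median of 1342 molecules per cell.

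Dct, a pigment enzyme gene of melanocytes, was found in every immune class, from 10.3 CPM in cDC1-like cells to 77.8 in eosinophil-like cells, against 8988 in melanoma-like cells. Free RNA from melanoma cells should carry their ratio of Tyrp1, another pigment gene, to Dct, which was 0.482, and all 10 immune classes with enough molecules lay within 2-fold of it, at 0.77 to 1.44 times. That ratio cannot tell free RNA from other routes by which melanoma transcripts reach an immune cell. Of the 1355 Dct molecules, 13.4% (11.6% to 15.3%) lay in cells with 5 or more, so most were spread thinly. Whole melanoma cells captured with immune cells cannot be excluded, since such pairs could have clustered as melanoma-like cells. Low levels, in immune classes, of any gene abundant in melanoma cells may therefore be melanoma transcripts, and no biological explanation was tested.

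Among the 62 single-tag cells with CCR7+ DC and T receptor transcripts, Icos was found in 83.9%, Ctla4 in 74.2%, Pdcd1 in 61.3%, Cd4 in 46.8%, Cd8b1 in 46.8% and Foxp3, the regulatory T cell factor, in 38.7%. Among the 29 such multiplets by tag, Icos was found in 93.1%, Ctla4 in 82.8%, Pdcd1 in 41.4%, Cd4 in 55.2%, Cd8b1 in 41.4% and Foxp3 in 44.8%.

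In macrophage-like cells, the class with most cells, the 5 genes of largest spread between tags out of 9877 were Clic5 (0.22, 9.02 and 3.10 CPM in tags 8, 9 and 10), AC132235.2 (0.22, 6.29 and 0.17), Lyve1 (52.8, 1.47 and 40.3), Vsig4 (0.22, 0.21 and 7.05) and Fcrl5 (2.86, 0.42 and 11.9). Lyve1, a hyaluronan receptor of resident macrophages, came from 50 cells with up to 73 molecules in 1 of them, Vsig4 from 4 cells, and AC132235.2 from 6 cells with 27 molecules in 1 of them. The spread was not tested, since each tag was seen once.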
